A study of Mus musculus with 4 samples.

How the data were processed

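Gene expression was measured in single cells of 4 samples described as mouse tumours, 2 wild-type and 2 Za-mutant. Droplet sequencing with the 10x Genomics 3' kit (version 2, per the labels) was used. Groups were taken from the genotype field. For both Za-mutant samples, but neither wild-type sample, the library name in the file names differs from the one in the labels, so their values rest on the sample under which each file was deposited. The titles of the Za-mutant samples carry the word Lyz in its place, and the design text places the mutation in the transplanted cells; what Lyz stands for is not given in the sources used here. The authors deposited filtered matrices of UMI counts, which are whole numbers per gene and barcode and not normalised, over 32285 features. The matrices were written by Cell Ranger 9.0.1, per the file headers. The submitters' processing notes name Cell Ranger, STARsolo, alevin and Seurat and the builds GRCh38 and GRCm38, without roles. Feature identifiers of the genes given with coordinates were the same in the GENCODE annotation of GRCm38, from which positions were taken.

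Cells with at least 500 genes and at most 20% mitochondrial UMIs were kept, and cells called doublets by Scrublet (expected rate 0.008 per 1000 cells) were left out: 4.03%, 4.53%, 3.75% and 3.40% of filtered cells. Clustering used scanpy 1.11.5 with 3000 variable genes, 40 principal components, 20 neighbours and Leiden resolution 1 (leidenalg 0.10.2), giving 42 clusters. Clusters were named from marker lists fixed before the data were examined: a cluster took the class with the highest score and had to raise at least 3 detected markers. Sub-clusters of T and NK cells and of monocytes and macrophages had only to detect 3 markers in at least 10% of cells. A cluster stayed unnamed where its leading genes went against its name or over 40% of its cells were doublets. The naming rule was then revised after the clusters were seen. Clusters with Rhox5 in at least 40% and Xist in at most 15% of cells were named Rhox5+, although their highest score from the fixed markers was for fibroblasts. The class planned as malignant, defined by keratins and Epcam, is called epithelial, since its fixed list is one of epithelial genes. Its leading genes were Prlr, Wfdc2, Krt19 and Csn3, and in 3 libraries it held 16 to 54 cells. The planned comparisons of malignant cells and of neutrophils could not be run, as they did not reach 50 cells in every library. Clusters left unnamed made up 3.48%, 4.80%, 2.63% and 6.69% of cells, and within monocytes and macrophages 27.4%, 55.4%, 62.1% and 6.48% belonged to neither named sub-class. A difference from other work can come from these rebuilt names. In droplets, free RNA gives UMIs to cells that do not express a gene: Rhox5 in T and NK cells put it at 4.68%, 2.78% and 3.28% of their UMIs in the 3 libraries with Rhox5+ cells.

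UMI counts were summed per library and class, for classes with at least 50 cells in each library, and tested with edgeR 4.0.16 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg, threshold 0.05) in R 4.3.3. The log2 fold is Za-mutant minus wild-type, and single-gene CPM beside it are normalised by edgeR. The Rhox5+ class, which replicate 2 of the Za-mutant group lacks, was fitted on 3 libraries. The 28 gene lists were tested by camera (limma 3.58.1, preset correlation 0.01, at least 5 members tested), with an estimated correlation and fry as alternatives; the list of Y-linked genes and Xist had too few members in all 10 classes. Shares of cells were tested with edgeR on cell numbers and by an exact permutation test. DESeq2 1.42.0 was the other tool. Intervals and floors cover counting error only, with a floor of 3 counts. Intervals at 95% for single shares were exact binomial.

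Named genes followed a rule set before the data were examined: Adar, 2 to 4 members of each list spoken of, those with the smallest p in that class, and, per main comparison, up to 10 higher and 10 lower genes past the threshold with a mean of at least 10 CPM and non-overlapping groups (3 and 3 in other classes), leaving out predicted, mitochondrial and ribosomal protein genes. Few genes passed. Genes named outside the rule are said to have been chosen after their values were seen: Rhox5, Xist, Epcam, Malat1, the immunoglobulin genes, Ccl21a and Lyz2 among myeloid cells.

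The fitting code was tested on simulated counts with 200 genes changed and a dispersion of 0.02. For the whole tumour, edgeR recovered 90% of the genes changed 2-fold and 100% of those changed 4-fold among 20420 genes tested; for monocytes and macrophages 91% and 100% among 14840; for CD8 T cells 84% and 100% among 11970; and for Rhox5+ cells, 2 against 1 library, 71% and 100% among 17350. False calls were 17, 10, 8 and 2. The fits to the deposited counts had a common biological coefficient of variation (the square root of the dispersion) of 0.619 for the whole tumour, 0.366 for monocytes and macrophages, 0.342 for CD8 T cells and 0.220 for Rhox5+ cells. The simulated dispersion of 0.02 was smaller than in each of these fits. The percentages recovered therefore do not tell how many changed genes could be found in the deposited counts. Alternatives planned before the data were examined were DESeq2, RLE size factors, no filter on low counts, doublets kept, a stricter cell filter (at least 1000 genes, at most 10% mitochondrial), Leiden resolution 2 (57 clusters), the replicate number as a block and each library left out. The fits of Rhox5+ cells and of the interaction on 3 libraries, and DESeq2 on 3 libraries, were added after the data were seen.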

Results

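Single-cell RNA profiles were collected from 4 samples, described as tumours grown from MC38, a mouse colon adenocarcinoma line, placed on the back of C57 mice. All 4 samples were described as treated with an antibody against PD-1, a checkpoint receptor of T cells. Of these, 2 were labelled wild-type and 2 Za-mutant. The series concerns the p150 isoform of ADAR1, an enzyme that edits double-stranded RNA, so the comparison asks how the Za-mutant tumours differed from wild-type tumours under this treatment. The 4 libraries held 24367 and 26530 barcodes (wild-type replicates 1 and 2) and 23581 and 18591 barcodes (Za-mutant replicates 1 and 2). Their totals were 323499798, 321129676, 307996991 and 196612938 unique molecular identifiers (UMIs), in the same order. After filtering, 21546, 22997, 21590 and 17355 cells remained, with medians of 7546, 5581, 6406 and 4820 UMIs per cell. The labels name no animal, so p-values measure the spread between these libraries.

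The libraries differed in which cells they held. A class named Rhox5+, after an X-linked homeobox gene (ENSMUSG00000095180, chromosome X, 37804842 to 37808876 in GRCm38), made up 50.5% and 27.6% of wild-type cells and 33.4% of cells in Za-mutant replicate 1. The library labelled Za-mutant replicate 2 held 3 such cells, or 0.0173% of its cells (exact 95% binomial interval 0.00356% to 0.0505%). Rhox5+ cells carried 2.69 to 3.60 CPM (UMIs scaled to the total of the class) of Xist, the RNA that coats the inactive X chromosome of female cells, in the 3 libraries that held them, against 570 to 753 CPM in monocytes and macrophages of all 4. Xist in at most 15% of cells was a condition for naming a cluster Rhox5+, so low Xist in this class follows from its definition. The same library was set apart by epithelial cells, which formed 10.2% of it (1769 cells, exact 95% binomial interval 9.75% to 10.7%) and 0.0835%, 0.235% and 0.0741% of the other 3. These cells carried 1514 CPM of Xist and 1865 CPM of Epcam, an epithelial adhesion molecule. Over the whole of that library, Malat1, a nuclear RNA, stood at 14791 CPM, against 4051 to 4394 CPM in the other 3, and the median mitochondrial share was 0.690% against 1.02% to 1.32%. Below it is called Za-mutant replicate 2 after its label and counted with the Za-mutant libraries, without its identity being settled.

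**Figure D1:**
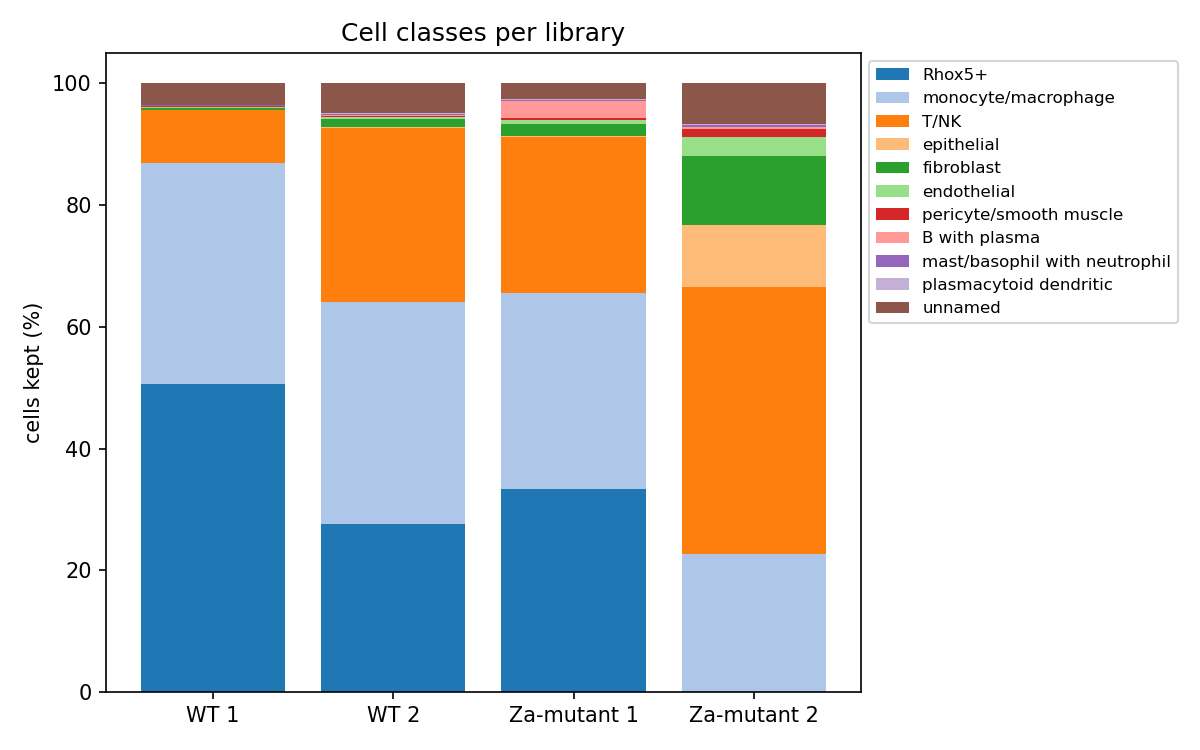
Share of kept cells (%, vertical axis) in each cell class (colours) for each of the 4 libraries (bars). Rhox5+ cells make up 27.6% to 50.5% of 3 libraries and are nearly missing from the library labelled Za-mutant replicate 2, where epithelial cells reach 10.2%.

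Naive and central memory T cells, recognised by genes such as Lef1 and Ccr7, were the 1 class of 18 whose share passed the test between genotypes. They formed 19.2% and 14.8% of T and NK cells in the Za-mutant libraries and 0.848% and 0.639% in the wild-type libraries (mean 17.0% ± 3.06 against 0.743% ± 0.148, SD, n = 2 per group). The log2 fold was 4.53 (edgeR quasi-likelihood test on cell numbers, adjusted p = 0.0113), and 4.71 without Za-mutant replicate 2 (edgeR, adjusted p = 0.0287). Sub-cluster 6 held most of these cells in Za-mutant replicate 1 and sub-cluster 5 in replicate 2. The libraries were clustered without being aligned, so the share also depends on how clusters were cut and named. Summed over all T and NK cells, the naive T genes Lef1 and Tcf7 had smaller log2 folds, 1.31 and 0.68. S1pr1, another marker of this class, had 0.83, and 0.024 without Za-mutant replicate 1. It stood at 36.1 CPM in Za-mutant replicate 2, between the wild-type libraries (25.4 and 43.7 CPM). The median of the naive T list in T and NK cells changed sign with a library left out. At Leiden resolution 2 the log2 fold of the share was 4.52 (edgeR, adjusted p = 0.0366). With wild-type replicate 1 or 2 left out, the log2 fold was 4.73 or 4.32 and no class passed (edgeR, adjusted p = 0.167 and 0.194). The exact two-sided permutation test gave p = 0.333, the smallest p that 2 against 2 allows.

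Regulatory T cells made up 6.74% and 6.59% of T and NK cells in the Za-mutant libraries, against 10.3% and 11.0% in wild-type, without passing correction (log2 fold -0.68, edgeR, adjusted p = 0.221). T and NK cells as a whole formed 8.75% and 28.6% of wild-type and 25.8% and 43.9% of Za-mutant cells (log2 fold 0.90, edgeR, adjusted p = 0.733; 0.46 without Za-mutant replicate 2, adjusted p = 0.857). Za-mutant replicate 1 thus lay between the 2 wild-type libraries. CD8 T cells formed 51.3% and 61.5% of T and NK cells in wild-type and 52.6% and 42.3% in Za-mutant libraries (log2 fold -0.25, edgeR, adjusted p = 0.633; -0.10 without Za-mutant replicate 2). Fibroblasts formed 0.357% and 1.24% of wild-type and 2.01% and 11.4% of Za-mutant cells and did not pass either (log2 fold 3.07, edgeR, adjusted p = 0.266; 1.33 without Za-mutant replicate 2, adjusted p = 0.722). Of 18 classes tested, edgeR called 1, with 2 at an unadjusted p under 0.05. DESeq2 called 2, the naive and central memory T cells and epithelial cells (log2 fold 5.01, DESeq2, adjusted p = 0.0290), the latter at -1.10 without Za-mutant replicate 2 (edgeR, adjusted p = 0.722). Of the 5 classes tested with immune cells as denominator, B cells with plasma cells passed (log2 fold 3.53, edgeR, adjusted p = 0.0183). As a share of all cells they did not (3.65, edgeR, adjusted p = 0.266). They formed 0.0882% and 0.165% of all cells in wild-type and 2.80% and 0.398% in Za-mutant libraries. Without Za-mutant replicate 1 that fold was 1.64 (edgeR, adjusted p = 0.238).

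Adar, which encodes ADAR1 (ENSMUSG00000027951, chromosome 3, 89715022 to 89753446 in GRCm38), was read first in every library. Over all kept cells it stood at 23.2 and 29.6 CPM in wild-type and 29.4 and 69.0 CPM in Za-mutant libraries. In Rhox5+ cells normalised Adar was 18.4 and 20.2 CPM in wild-type and 21.0 CPM in Za-mutant replicate 1 (log2 fold 0.13 ± 0.23, SE, edgeR, adjusted p = 1.00). In monocytes and macrophages the log2 fold was 0.22 ± 0.24 (SE, edgeR, adjusted p = 0.945), and in CD8 T cells 0.63 ± 0.42 (SE, edgeR, adjusted p = 0.983). Without Za-mutant replicate 2 these were -0.037 and 0.083. The highest folds were 1.39 ± 0.39 in fibroblasts (SE, edgeR, adjusted p = 1.00) and 1.07 ± 0.42 in CD4 T cells (SE, edgeR, adjusted p = 1.00), and without that library they were 0.94 and 0.62. Each Za-mutant library lay above both wild-type libraries in these 2 classes. Counts at the 3' end of a gene tell neither its isoforms apart nor a changed base, so these values do not check the genotype labels.

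By camera, genes of the type I interferon response were higher in Za-mutant CD8 T cells, NK cells, fibroblasts and macrophages, while calls in regulatory T cells and monocytes ended without Za-mutant replicate 1. None of these calls held with an estimated correlation between genes (adjusted p of 0.790 or above with an estimated correlation). Ifi44, an interferon-induced gene (ENSMUSG00000028037, chromosome 3, 151730922 to 151749960 in GRCm38), was 65.7 and 136 CPM in Za-mutant CD8 T cells against 8.91 and 6.35 CPM in wild-type (log2 fold 3.76 ± 0.48, SE, edgeR, adjusted p = 0.983). The list of type I interferon-stimulated genes passed camera upwards in 8 of 10 tested classes with 4 libraries and in 10 of 10 without Za-mutant replicate 2. With an estimated correlation it passed in none (adjusted p of 0.790 or above with 4 libraries and 0.914 or above without that library). With 4 libraries its median log2 fold was 1.00 in fibroblasts, 0.78 in CD8 T cells, 0.73 in NK cells, 0.70 in all T and NK cells, 0.42 in regulatory T cells and monocytes, 0.41 in macrophages and 0.25 in monocytes and macrophages together. Without that library these medians were 0.89, 0.40, 0.25, 0.55, 0.52 and 0.85, 0.37 and 0.31. In monocytes the list's median in Za-mutant replicate 2 differed by -0.13 from the wild-type mean. That library held 112 monocytes, against 2153 and 1489 in the wild-type libraries and 960 in Za-mutant replicate 1. Without Za-mutant replicate 1 the median was -0.32 in monocytes (camera, adjusted p = 0.677), 0.22 in regulatory T cells (camera, adjusted p = 0.142) and 0.19 in monocytes and macrophages together (camera, adjusted p = 0.0573). In monocytes the call also ended at Leiden resolution 2 (0.12, camera, adjusted p = 0.180). In CD4 T cells (median log2 fold 0.10, camera, adjusted p = 0.2997) and in the whole tumour (0.15, camera, adjusted p = 0.361) the list did not pass with 4 libraries. No list passed in any class with an estimated correlation or by fry, so each list call here rests on the preset correlation of 0.01. The 10 classes overlap. Cells of a sub-class are counted again in T and NK cells or in monocytes and macrophages, and in the whole tumour. Counts of classes are thus not counts of separate results.

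**Figure D2:**
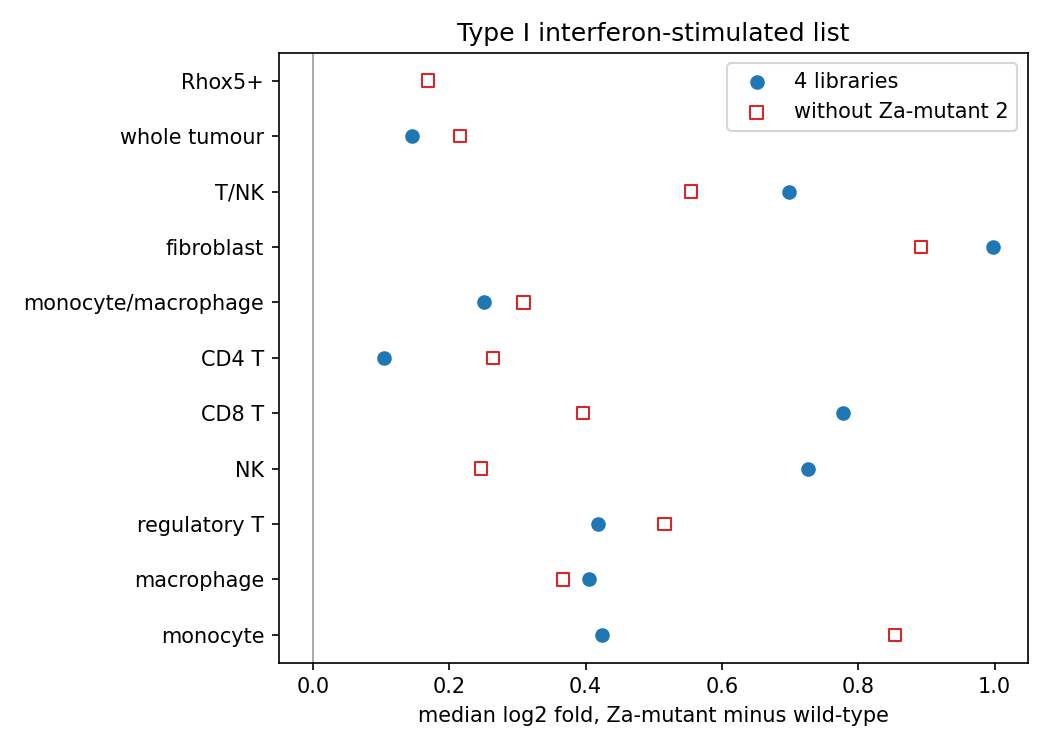
Median log2 fold (Za-mutant minus wild-type, horizontal axis) of the type I interferon-stimulated list in each cell class (vertical axis), with 4 libraries (filled circles) and without Za-mutant replicate 2 (open squares). The Rhox5+ class is drawn only without that library, at 0.17. Every median lies above 0, up to 1.00 in fibroblasts.

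Single members passed over all genes where the library labelled Za-mutant replicate 2 was left out. Those fits set 1 Za-mutant library against 2 wild-type libraries, so their p-values hold no spread between Za-mutant libraries. In monocytes the common biological coefficient of variation was 0.142 in that fit and 0.297 with 4 libraries. In monocytes 16 of 38 members were then higher over all genes and 31 when adjusted over the list alone. Among them were Ifi44 (log2 fold 2.32, edgeR, adjusted p = 2.66e-07), Oas1g (1.57, edgeR, adjusted p = 0.000227) and Oas2 (1.00, edgeR, adjusted p = 0.0135), the last 2 of the family of oligoadenylate synthetases. With 4 libraries these were 1.87, 1.41 and 1.03 (edgeR, adjusted p = 0.929 each). DESeq2 on the 3 libraries called the first 2 but not Oas2 (adjusted p = 0.227). Regulatory T cells had 7 of 36 such members (12 adjusted over the list alone), T and NK cells 4 of 38 (16), CD8 T cells 3 of 38 (5), CD4 T cells 2 of 36 (4), NK cells 1 of 34 (1) and fibroblasts 1 of 36 (12). In macrophages, in monocytes and macrophages together and in the whole tumour edgeR called 0 of 38 members, also when adjusted over the list alone. The 3 in CD8 T cells were Ifi44 (3.16, edgeR, adjusted p = 3.83e-13), Oasl1 (2.45, edgeR, adjusted p = 4.99e-06) and Usp18, which removes ISG15 from proteins (1.43, edgeR, adjusted p = 0.0120). With 4 libraries these were 3.76, 2.99 and 1.56 (edgeR, adjusted p = 0.983 each). DESeq2 on the 3 libraries called only Ifi44 of them. With 4 libraries the counts adjusted over the list alone were 23 in fibroblasts, 13 in T and NK cells, 3 in CD8 T cells, 3 in regulatory T cells, 1 in NK cells, 1 in CD4 T cells and 0 in the other classes.

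Monocytes and macrophages were a main comparison. Ifi44 (106 and 116 CPM in Za-mutant, 56.5 and 46.5 in wild-type, log2 fold 1.11 ± 0.21, SE, edgeR, adjusted p = 0.945) and Ifit1, an inhibitor of viral translation (0.60 ± 0.19, SE), were among the interferon-stimulated members with the smallest p (list median 0.25, camera, adjusted p = 2.7e-06; adjusted p = 0.790 with an estimated correlation), and the list did not pass without Za-mutant replicate 1 (0.19, camera, adjusted p = 0.0573). MHC class II presentation genes were lower by camera (13 members, median log2 fold -0.71, adjusted p = 4.56e-05; adjusted p = 0.790 with an estimated correlation), with Cd80, a costimulatory ligand, at 36.3 and 23.9 CPM against 73.1 and 73.4 (-1.28 ± 0.27, SE). Without Za-mutant replicate 2 the list stood at -0.21 (camera, adjusted p = 0.0141; adjusted p = 0.914 with an estimated correlation) and Cd80 at -1.01 (edgeR, adjusted p = 0.966). Hypoxia and glycolysis genes were lower (22 members, median -0.56, camera, adjusted p = 2.28e-05; adjusted p = 0.790 with an estimated correlation), but not without Za-mutant replicate 2 (median -0.042, camera, adjusted p = 0.152). Its members Egln3 and Ddit4 had log2 folds of -1.22 ± 0.37 and -1.12 ± 0.38 (SE, edgeR, adjusted p = 0.945 each), and -0.85 and -0.71 without that library. The G2/M list was lower (median -0.77, camera, adjusted p = 1.9e-06; adjusted p = 0.790 with an estimated correlation) and stood at 0.021 without that library. Haemoglobin genes, markers of red cells, were higher (5 members, median 3.85, camera, adjusted p = 8.53e-06; adjusted p = 0.790 with an estimated correlation), and at 2.50 without it (camera, adjusted p = 0.000547; adjusted p = 0.914 with an estimated correlation). Over all genes edgeR called 0 of 14738, with 260 at an unadjusted p under 0.05 and 12 called by DESeq2. Without Za-mutant replicate 2 edgeR called 0, with 382 at an unadjusted p under 0.05, and DESeq2 32. Different clusters held this class: 3282 cells of cluster 8 came from Za-mutant replicate 2, while cluster 0 held 4464 cells of Za-mutant replicate 1 and 6 of replicate 2.

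Lyz2, lysozyme M of myeloid cells (ENSMUSG00000069516, chromosome 10, 117277331 to 117282321 in GRCm38) and chosen after its values were seen, was 5032 and 3060 CPM in Za-mutant macrophages against 8707 and 15703 CPM in wild-type. The log2 fold was -1.59 ± 0.45 (SE, edgeR, adjusted p = 0.907) in macrophages and -1.38 ± 0.46 (SE, edgeR, adjusted p = 0.929) in monocytes. Without Za-mutant replicate 2 it passed in monocytes (-1.08, edgeR, adjusted p = 0.0399), but not in macrophages (-1.28, edgeR, adjusted p = 1.00) or in monocytes and macrophages together (-1.58, edgeR, adjusted p = 1.00).

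**Figure D3:**
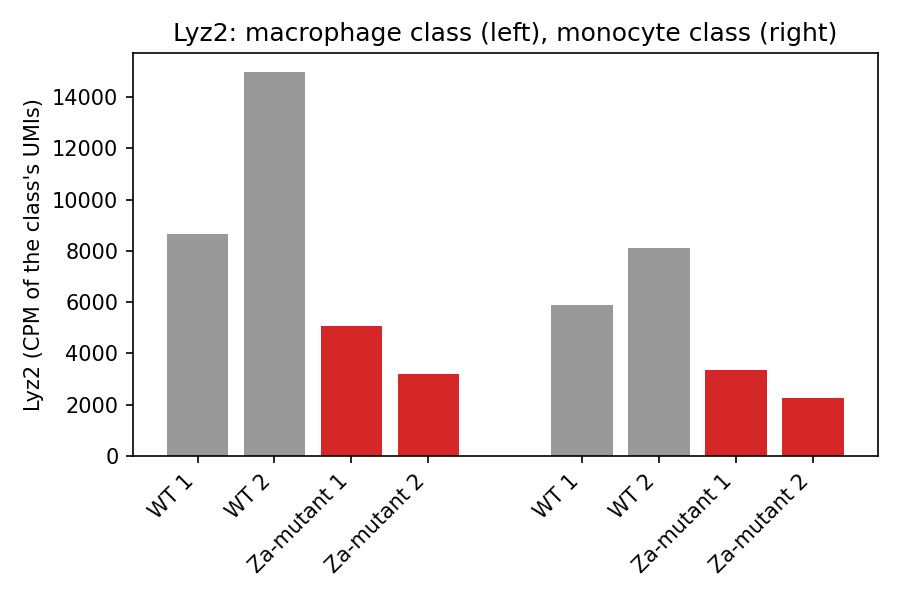
Lyz2 (CPM of the class's UMIs, vertical axis) in macrophages (left) and monocytes (right) of each library, wild-type in grey and Za-mutant in red, before edgeR's normalisation. Each bar is one library, and each Za-mutant bar lies below each wild-type bar of its class.

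In CD8 T cells, another main comparison (of T and NK cells, clusters 7, 19, 20, 24 and 30 came almost wholly from Za-mutant replicate 2), stress-response genes were also higher: Hspa1b, a heat-shock chaperone, was 44.1 and 547 CPM in Za-mutant and 14.9 and 15.6 in wild-type (log2 fold 4.27 ± 1.10, SE, edgeR, adjusted p = 0.983; 1.54 without Za-mutant replicate 2, adjusted p = 0.0120, where DESeq2 did not call it). The dissociation and immediate early list was higher by camera (21 members, median 0.66, adjusted p = 7.5e-07; adjusted p = 0.790 with an estimated correlation), and at 0.15 without that library (camera, adjusted p = 7.87e-05; adjusted p = 0.914 with an estimated correlation). G2/M (median -0.95), S phase (-0.61) and MHC class II (-0.83) genes were lower by camera (adjusted p = 5.27e-06, 0.00016 and 0.00152; each with adjusted p = 0.790 with an estimated correlation), and without Za-mutant replicate 2 none of these 3 passed (-0.34, -0.32 and -0.35; camera, adjusted p = 0.208, 0.0707 and 0.0973). Genes marking free RNA of abundant cell types were lower in the same cells (median -0.56, camera, adjusted p = 0.0138; adjusted p = 0.790 with an estimated correlation), and at -0.65 without that library (camera, adjusted p = 0.0104; adjusted p = 0.914 with an estimated correlation). Of the class II genes, H2-Eb1 stood at 47.8 and 96.5 CPM in wild-type and 41.9 and 16.9 in Za-mutant CD8 T cells, against 2121 to 7714 CPM in monocytes and macrophages, and Lyz2 at 79.9 and 238 against 23.4 and 12.6 CPM in CD8 T cells. The cytotoxic effector list, with granzymes such as Gzmf and the receptor Klrd1, had a median of -0.27 (camera, adjusted p = 0.125) that became 0.22 without that library (camera, adjusted p = 0.000547; adjusted p = 0.914 with an estimated correlation). Over all genes edgeR called 0 of 11891, with 164 at an unadjusted p under 0.05 and 10 called by DESeq2. Without that library edgeR called 32 (18 higher, 14 lower) and DESeq2 3.

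Summed over the whole tumour, values mix cell shares with levels within cells. The epithelial list had a median log2 fold of 5.52 (camera, adjusted p = 0.000133; adjusted p = 0.790 with an estimated correlation) and of -0.80 without Za-mutant replicate 2 (camera, adjusted p = 0.00788; adjusted p = 0.919 with an estimated correlation). Endothelial genes were higher both with it (1.65, camera, adjusted p = 2.09e-05; adjusted p = 0.790 with an estimated correlation) and without it (0.51, camera, adjusted p = 0.000125; adjusted p = 0.914 with an estimated correlation). Among them Cdh5, Plvap and Emcn had log2 folds of 2.76 ± 0.92, 2.26 ± 0.78 and 1.95 ± 0.73 (SE, edgeR, adjusted p = 0.837 each), and 1.19, 1.21 and 1.05 without Za-mutant replicate 2 (edgeR, adjusted p = 1.00 each). Over all genes edgeR called 0 of 19562, with 417 at an unadjusted p under 0.05, while DESeq2 called 395. Without Za-mutant replicate 2 edgeR called 0, with 314 at an unadjusted p under 0.05, and DESeq2 39.

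Rhox5+ cells were compared between both wild-type libraries and Za-mutant replicate 1 alone, which is assumed to vary as wild-type libraries do. The genes past the threshold in edgeR were 5, all chosen after their values were seen: the immunoglobulin genes Ighg2c, Ighm, Iglv1 and Igkv9-120 and the chemokine Ccl21a. Ighg2c was at 0 in both wild-type sums and 9.01 CPM in Za-mutant replicate 1, at least 1341-fold higher against a floor of 3 counts over both. B cells with plasma cells, the source class of immunoglobulin, formed 2.80% of that library and 0.0882% and 0.165% of the wild-type libraries. The type I interferon-stimulated list had a median of 0.17 (38 members, camera, adjusted p = 0.000321; adjusted p = 0.852 with an estimated correlation), with Oasl1 at 31.9 CPM against 25.3 and 17.7. Of 17503 genes, 200 had an unadjusted p under 0.05, and DESeq2 called 11.

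CD4 T cells had 3 genes past the threshold with 4 libraries. The sums came from 93 and 542 cells in wild-type and 417 and 804 cells in Za-mutant libraries. Low CPM in wild-type replicate 1 therefore rest on few UMIs. Ifi44 rose from 16.3 and 9.43 to 164 and 158 CPM (log2 fold 3.88 ± 0.49, SE, edgeR, adjusted p = 0.0254). Lyz2 fell from 169 and 281 to 26.6 and 12.9 CPM (-3.60 ± 0.48, SE, edgeR, adjusted p = 0.0255), and Tff1, a secreted trefoil peptide, from 109 and 61.3 to 5.91 and 0.887 CPM (-4.83 ± 0.71, SE, edgeR, adjusted p = 0.0418). All 3 also passed without Za-mutant replicate 2 (3.94, -3.14 and -3.63, edgeR, adjusted p = 4.83e-15, 2.67e-09 and 9.94e-07). On those 3 libraries DESeq2 called only Lyz2, with log2 folds of 3.84 for Ifi44 and -3.81 for Tff1. At Leiden resolution 2 only Ifi44 passed, with Lyz2 at -3.26 (edgeR, adjusted p = 0.416) and Tff1 at -4.69 (edgeR, adjusted p = 0.117). Tff1 was not called under the stricter cell filter (-5.02, edgeR, adjusted p = 0.0534), nor Ifi44 without wild-type replicate 2 (3.31). Over all kept cells Lyz2 stood at 1050 and 2058 CPM in wild-type and 529 and 987 CPM in Za-mutant libraries. The free RNA was put at 4.68% and 2.78% of UMIs of wild-type T and NK cells and 3.28% in Za-mutant replicate 1. Such shares of the values over all kept cells lie below the Lyz2 CPM of CD4 T cells in each of these libraries. Free RNA with the make-up of all kept cells would thus not give all of that Lyz2. Genes marking free RNA were lower in CD4 T cells (median -1.26, camera, adjusted p = 1.24e-06; adjusted p = 0.790 with an estimated correlation; -0.85 without Za-mutant replicate 2). In the other classes edgeR called 0 genes: T and NK cells (238 at an unadjusted p under 0.05, 16 by DESeq2), fibroblasts (332, 9), NK cells (154, 2), regulatory T cells (158, 2), macrophages (391, 18) and monocytes (339, 27). Without Za-mutant replicate 2 edgeR called 60, 19, 38, 17, 0 and 110 genes in these classes, and 28 in CD4 T cells, against 10, 2, 5, 1, 12, 37 and 1 by DESeq2. Among those of T and NK cells, Lef1 (1.47, edgeR, adjusted p = 0.0174) and S1pr1 (1.34, edgeR, adjusted p = 0.0207), genes of naive T cells, were higher, and in NK cells so was Pdcd1, which encodes PD-1 (1.38, edgeR, adjusted p = 0.00883). With 4 libraries these were 1.31, 0.83 and 1.34 (edgeR, adjusted p = 0.944, 0.944 and 0.999). S1pr1 in Za-mutant replicate 2 (36.1 CPM) lay between the wild-type libraries (25.4 and 43.7 CPM). DESeq2 on the 3 libraries called none of them (adjusted p = 0.603, 0.684 and 1.00).

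Whether the genotype difference itself differed between Rhox5+ cells and monocytes and macrophages was tested by an interaction without Za-mutant replicate 2. Ighm was the 1 gene called of 17891 (log2 difference 4.21, edgeR, adjusted p = 0.0209), with 350 at an unadjusted p under 0.05. No gene was called under the stricter cell filter (346 at an unadjusted p under 0.05). The haemoglobin list differed by -2.85 (camera, adjusted p = 3.07e-05; unadjusted p = 0.168 with an estimated correlation) and the dissociation list by 0.46 (camera, adjusted p = 0.00245; unadjusted p = 0.152 with an estimated correlation). For the type I interferon-stimulated list the difference was -0.096 and did not pass (camera, adjusted p = 0.243).

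Other lists passed camera in several of the 10 classes, none with an estimated correlation (adjusted p of 0.790 or above). These classes overlap in cells, so the counts below are not counts of separate results. Fewer classes were tested, with 4 libraries and without Za-mutant replicate 2, for haemoglobin genes (2 and 2), epithelial genes (5 and 4), angiogenic genes (6 and 7) and regulatory T genes (9 and 9). For cytotoxic, suppressive neutrophil and alternatively activated macrophage genes 9 and 10 were tested. MHC class II genes were lower in 9 classes with 4 libraries and in 6 without Za-mutant replicate 2, and mitochondrially encoded genes in 10 and 8. S phase genes were lower in 9 and 4 (higher in 0 and 1), G2/M genes in 7 and 3, and hypoxia and glycolysis genes in 9 and 0. Genes marking free RNA of abundant cell types were lower in 7 and 7, suppressive neutrophil genes in 5 and 7, and complement and lysosome genes in 5 and 4 (higher in 2 and 1). Dissociation and immediate early genes were higher in 7 and 4, naive and memory T genes in 3 and 5 (lower in 0 and 1), exhaustion genes in 2 and 2 (lower in 1 and 1) and haemoglobin genes in 2 and 2. Interferon-gamma-induced genes were lower in 5 and 0 (higher in 1 and 1), and cytotoxic genes were lower in 1 and 0 and higher in 0 and 6. MHC class I genes were higher in 1 and 3 (lower in 1 and 0), Z-RNA sensing and necroptosis genes in 1 and 3, angiogenic genes in 1 and 3, epithelial genes in 1 and 0 (lower in 0 and 1), NF-kB targets in 1 and 1, and regulatory T genes in 1 and 1 (lower in 1 and 0). T and NK attracting chemokines were lower in 1 and 0 (higher in 0 and 2), myeloid attracting factors in 3 and 1 (higher in 0 and 1), alternatively activated macrophage genes in 0 and 2, matrix genes in 1 and 0, and unfolded protein response genes in 1 and 0 (higher in 0 and 1). The p53 targets passed in 0 and 0 classes.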

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

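The tests of the missing Rhox5+ cells, of replicate 2 alone and of Lyz2, and the interaction without replicate 2, were chosen after the result was seen. Those of free RNA and of variation between animals were set before.

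The difference between genotypes, without Za-mutant replicate 2, differed between Rhox5+ cells and monocytes and macrophages for Ighm by 4.21 on the log2 scale (edgeR interaction, adjusted p = 0.0209; 0 genes called under the stricter cell filter, 346 at an unadjusted p under 0.05), for the haemoglobin list by -2.85 and for the dissociation and immediate early list by 0.46. Both list differences passed camera, but not with an estimated correlation (unadjusted p = 0.168 and 0.152 with an estimated correlation).

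The library labelled Za-mutant replicate 2 held 10.2% epithelial cells, which no comparison of expression within a class uses, and 3 Rhox5+ cells. Their removal by the cell filters used here is excluded: over all its deposited barcodes Rhox5 stood at 0.0769% of the lowest other library. The deposited matrices were already filtered, so this does not cover barcodes removed before deposit. Rhox5+ cells present in the tissue but not captured would leave free RNA, but Rhox5 in T and NK cells was 1.51% of the lowest other library. Tissue of another kind and a tumour that had regressed cannot be told apart by the 10.2% epithelial share, since no label or other library separates them. A mislabelled sample was not tested, and the library names in the files of both Za-mutant samples differ from those in their labels.

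The type I interferon-stimulated list was higher in 8 classes with 4 libraries, of which 3 lost the call without Za-mutant replicate 1 (monocytes, now at -0.32, regulatory T cells at 0.22 and monocytes with macrophages at 0.19). Without replicate 2 the list was past the camera threshold in 8 of those 8 classes, and with an estimated correlation in none of them. This cannot exclude that replicate 2 carried much of the rise. The test sets 1 Za-mutant library against 2 wild-type libraries and rests on the preset correlation. The list's median difference from the wild-type mean was above 0 in replicate 1 in all 8 classes. Of these, the T and NK class and the monocyte and macrophage class hold the cells of their sub-classes again. In replicates 1 and 2 it was 0.19 and 1.24 in NK cells and 0.41 and 1.16 in CD8 T cells. In monocytes, of which replicate 2 held 112, it was 0.87 and -0.13, and in regulatory T cells 0.49 and 0.29. Free RNA taken up by T and NK droplets could give a median of 0.463% of the change over 38 members in T and NK cells of Za-mutant replicate 1; the free RNA of replicate 2, which lacks Rhox5+ cells, could not be estimated. Variation between animals of one genotype remains open: the wild-type libraries differed by as much as Za-mutant replicate 1 from their mean in 1 of 8 classes (macrophages, 0.421 against 0.420), and 2 wild-type libraries are too few to exclude it. In fibroblasts, with the highest list median, they differed by nearly as much (-0.78 against 0.88), as in NK cells (-0.15 against 0.19). They differed by less in T and NK cells (-0.056 against 0.53), CD8 T cells (0.030 against 0.41) and monocytes (0.028 against 0.87). The genotype stays a candidate explanation, as a hypothesis.

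Lyz2 was lower in each Za-mutant library than in each wild-type library within macrophages and within monocytes, by at least 0.77 on the log2 scale (-0.77). Fewer monocytes among the macrophages therefore cannot be the whole cause. Before edgeR's normalisation, Lyz2 was also higher in macrophages than in monocytes of each library. The values were 8665 against 5907 and 14974 against 8110 CPM in wild-type replicates 1 and 2. In Za-mutant replicates 1 and 2 they were 5068 against 3368 and 3190 against 2269 CPM. Macrophages in place of monocytes would thus raise Lyz2, which argues against this cause. Cells in neither named sub-class are not covered by these values. Of 127 abundant genes in macrophages and 143 in monocytes, 48 and 49 were lower without overlap, where chance alone gives 16.7% in one direction. By the gap from the highest Za-mutant to the lowest wild-type library, Lyz2 ranked 1 of 127 in macrophages and 7 of 143 in monocytes. A Lyz2 allele changed in the animal and a broader change of the myeloid cells cannot be told apart. Lyz2 was chosen because it was low, so its rank cannot speak for the allele. What the word Lyz in the Za-mutant titles stands for is not given.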

How the results depend on the processing

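DESeq2 on 3 libraries and the fits of Rhox5+ cells and of the interaction were chosen after the result was seen; the other alternatives were planned. Where leaving out a library left 1 sample in a group, that sample was assumed to vary like the other group. For CD4 T cells DESeq2 also called 3 genes. Doublets kept and the stricter cell filter left the counts of genes past the threshold within 1.5 times in all 11 classes. Causes were not tested.

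Genes past the threshold by DESeq2 were 395 for the whole tumour, 16 for T and NK cells, 9 for fibroblasts, 12 for monocytes and macrophages, 10 for CD8 T cells, 2 for NK cells, 2 for regulatory T cells, 18 for macrophages, 27 for monocytes and 11 for Rhox5+ cells. DESeq2 on 3 libraries, without Za-mutant replicate 2, gave 39, 10, 2, 32, 3, 5, 1, 12 and 37 for the first 9 of these and 1 for CD4 T cells. With no filter on low counts edgeR called 149 for T and NK cells, 93 for fibroblasts, 21 for CD4 T cells, 99 for CD8 T cells, 48 for NK cells, 32 for regulatory T cells, 448 for macrophages, 224 for monocytes and 53 for Rhox5+ cells. RLE size factors gave 2 for Rhox5+ cells, and Leiden resolution 2 gave 1 for CD4 T cells, higher.

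The numbers 1 and 2 are names only, since no label ties same-numbered libraries to a shared animal, day or litter, and 2 pairs are too few to tell; deviations of same-numbered libraries correlated at 0.0321 to 0.527 across genes over the 10 classes. With the replicate number as a replicate block, edgeR called 149 genes for fibroblasts, 55 for CD4 T cells, 7 for CD8 T cells, 5 for NK cells and 98 for regulatory T cells.

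With each library left out in turn, the lowest and highest counts were 0 and 8590 for the whole tumour, 0 and 2689 for T and NK cells, 0 and 137 for fibroblasts, 0 and 1570 for monocytes and macrophages, 2 and 676 for CD4 T cells, 18 and 1753 for CD8 T cells, 0 and 2163 for NK cells, 5 and 2883 for regulatory T cells and 0 and 2468 for monocytes. Each highest count came without Za-mutant replicate 1, which leaves the library labelled Za-mutant replicate 2 against both wild-type libraries. Cell classes called ranged from 0 to 1, and DESeq2 called 2, epithelial cells being the added one. With immune cells as denominator, which tests no T cell classes, the 1 class called was B cells with plasma cells. The interaction called 2 genes with doublets kept, 0 with the stricter cell filter and 36 with no filter on low counts; leaving out a further library left no residual degrees of freedom, so no test was made, and likewise for Rhox5+ cells.

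With an estimated correlation 0 lists passed, and 0 by fry. The type I interferon-stimulated list kept its medians but lost its call under both: 0.17 in Rhox5+ cells, 0.70 in T and NK cells, 1.00 in fibroblasts, 0.25 in monocytes and macrophages, 0.78 in CD8 T cells, 0.73 in NK cells, 0.42 in regulatory T cells, 0.41 in macrophages and 0.42 in monocytes, and at Leiden resolution 2 its median in monocytes was 0.12 and did not pass (camera, adjusted p = 0.180). With each library left out its median ranged from -0.19 to 0.25 in the whole tumour, 0.19 to 0.32 in monocytes and macrophages, -0.26 to 0.47 in CD4 T cells, 0.22 to 0.52 in regulatory T cells and -0.32 to 0.85 in monocytes. In monocytes and macrophages, regulatory T cells and monocytes the call ended without Za-mutant replicate 1. Other medians that changed sign ranged from -1.51 to 0.034 for interferon-gamma-induced genes in monocytes and macrophages, -2.85 to 0.021 for G2/M genes there and -1.84 to 0.037 in CD8 T cells, -1.44 to 0.22 for cytotoxic genes in CD8 T cells and -1.41 to 0.092 in T and NK cells, -0.80 to 6.39 for epithelial genes in the whole tumour and -0.27 to 0.88 for naive T genes in T and NK cells.

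Single genes changed sign with a library left out, over ranges of -0.032 to 2.10 for Oasl1 in CD4 T cells, -3.87 to 0.35 for Gzmf and -1.64 to 0.19 for Klrd1 in CD8 T cells, -1.55 to 0.31 for Gzma and -1.68 to 0.050 for Klrd1 in T and NK cells, -0.064 to 0.52 for Adar in macrophages, -0.037 to 0.41 for Adar and -0.021 to 4.68 for Gpnmb in monocytes and macrophages, and -0.24 to 7.46 for Cldn4 and -0.31 to 6.67 for Ovol1 in the whole tumour. DESeq2 on 3 libraries gave 0.20 for Klrd1 in CD8 T cells and 0.045 in T and NK cells, -0.064 for Adar in macrophages and -0.040 in monocytes and macrophages, -0.025 for Gpnmb, -0.23 for Cldn4 and -0.31 for Ovol1; Leiden resolution 2 gave -0.028 for Adar in monocytes. Epithelial and Rhox5+ cells are too few in some libraries for a tested contrast over 4 libraries.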

Other observations

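The values here were read after the results were seen, and no test was chosen for them in advance.

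The library labelled Za-mutant replicate 2 carried transcripts that were low elsewhere. Prlr, the prolactin receptor, stood at 1751 CPM over all its cells, against 2.76, 8.57 and 2.82 CPM in the other libraries. Pgr, the progesterone receptor, stood at 158 CPM against 0.443, 0.617 and 0.134, and Csn3, kappa casein, at 111 CPM against 0.430, 1.88 and 0.359. Col1a1, a fibrillar collagen, stood at 2432 CPM against 64.3, 77.1 and 148, and Mki67, a proliferation marker, at 14.8 CPM against 85.9, 96.8 and 91.8. Shisal2b, like Rhox5, was nearly missing there, at 0.0163 CPM against 181 to 211 CPM in the others. Y-linked Eif2s3y was at 0 UMIs in all 4 libraries, which allows up to 0.00991 to 0.0163 CPM.

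Zbp1, a sensor of Z-form nucleic acid (ENSMUSG00000027514, chromosome 2, 173206612 to 173218923 in GRCm38), stood at 268 and 276 CPM in wild-type and 275 and 103 CPM in Za-mutant libraries over all cells.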
